A study of Drosophila melanogaster with 20 samples.

How the data were processed

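Transcript levels were measured in whole adult female Drosophila melanogaster of the Oregon-R strain on spotted cDNA arrays with 16896 features and 2 colour channels. The flies were 4 to 10 days old, were kept at 16 h of light and 8 h of dark and 60% humidity, and were sprayed in a Potter's tower with 2 mL of a solution in 99% ethanol or with 99% ethanol alone. RNA was taken 6 h later from about 240 flies per extract, and 80 µg of total RNA were labelled directly with Cy3 or Cy5. The treatments were an ethyl acetate extract of black pepper seed (Piper nigrum) at 0.2 mg/mL, the same extract at 0.1 mg/mL together with pyrethrin at 0.004 mg/mL, and pyrethrin at 0.04 mg/mL. Each array held a treated extract in 1 channel and an ethanol control extract in the other.

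The 20 arrays came from 12 treated extracts, 4 per treatment, which are the biological units here. Each unit of the pepper extract and of the combination was hybridised on 2 arrays with the dyes exchanged, which gave 8 arrays per treatment. The 4 pyrethrin units were hybridised on 1 array each, all with the treated RNA in Cy3, and shared 2 control extracts: control extract 3 for replicates 1 and 2, and control extract 4 for replicates 4 and 5. Groups were taken from the source names; the titles of 2 arrays of the pepper extract, the reverse arrays of replicates 3 and 4, name another study.

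The deposited values are log2 ratios; the base was inferred from their range, since the largest value in size was 14.3 and natural logarithms of 16-bit signals cannot exceed 11.1. The numerator of the ratio and the normalization used by the authors are not given in the sources used here. The array medians lay within 0.0365 of 0. The arrays held 13953 to 16853 values each, 5.36% of all values were missing, and the SD per array ran from 0.3463 to 0.6026. Signal and background intensities were not used here. The arrays differed in precision: neighbouring duplicate spots correlated at 0.172 (pepper extract replicate 4, reverse array) to 0.728 (combination replicate 6, reverse array). On the single array of pyrethrin replicate 4 they correlated at 0.19.

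The direction of the ratio was read by a rule fixed in advance. Within each treatment and dye orientation the mean array was subtracted, and the residuals of the 2 arrays of each unit were correlated across features. Values written as treated over control give positive correlations, and values written by channel give negative ones. The correlation was positive in 8 of 8 units, with a mean of 0.187 against -0.062 for arrays that were not partners, the highest mean of 576 possible pairings (exact one-sided permutation p = 0.00174). The unadjusted correlations of the partners were negative in 6 of 8 units (-0.202 to 0.269 over all), and arrays of opposite orientation of the pepper extract correlated at -0.5 to -0.14, which both a dye effect and values written by channel can give. The values were used as deposited, as treated over control; this direction is likely but is not stated in the labels.

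Each array's median was subtracted. Of the spots, 5666 carried a single gene symbol (2377 distinct symbols, all matched by gene identifier to the GCF_000001215.4 annotation, which was used for names and, in 1 check, for gene lengths), 152 carried several and 11078 carried none. Spots of the same single symbol were averaged per array, and every other spot was kept under its own number. Neighbouring spots were duplicates, since all 2909 annotated pairs shared their symbol. The 2 arrays of a dye exchange were averaged. Each pyrethrin array was corrected by adding, for each feature, the mean dye effect, which is how far each orientation lies from the mean of both, averaged over the 8 exchanged pairs (at least 4 pairs required). Features measured in at least 3 of 4 units of every treatment were tested, which left 11526 features, 2169 with a symbol and 9357 without.

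The 12 units entered 1 model in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with a mean per treatment, array weights by kind of unit (1.02 for averaged pairs, 0.966 for single arrays) and the control extract as a random block (correlation 0.0646). Each treatment was compared with 0, that is with its ethanol control, and the treatments were compared with each other. Moderated tests were two-sided, adjusted p-values follow Benjamini and Hochberg over all features of a comparison, and the threshold was 0.05. The doses of the combination differ from those of the single treatments, so the differences between treatments are not tests of an interaction.

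The named genes were to be the 10 largest rises and 10 largest falls past the threshold with 1 direction in every unit, up to 4 members past the threshold of each gene list, and the 5 largest in each direction for a difference. Where fewer than 5 genes with a symbol passed, as in every comparison here, the 10 with the smallest p-values are named. Cyp6a8, Cyp9b2 and Cyp12d1 were to be given in any case, because known publications of the study name induced P450 genes. Those publications may rest on these same arrays, so tests of Cyp12d1-p alone may not be independent of these data. Cyp12d1-p was measured, and the other two are not analysed here because no single-symbol spot carries their names.

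Gene lists with at least 3 measured members were tested with cameraPR on the moderated statistics, with an inter-gene correlation preset at 0.01 and again with a correlation estimated from residuals, and adjusted over 20 lists and 3 treatments. The groups, the model, the gene rule, the lists and the alternatives named in this paragraph were chosen before the data were examined. The alternatives were no centring, a common scale, single spots, stricter or looser limits on missing values, no dye correction or one from the swapped treatment with the nearest array numbers, a fit of 20 arrays with a dye coefficient, no block, no weights, robust variance shrinkage, a replicate block, leaving out the 2 arrays with foreign titles, and leaving out each unit. A reading of the values by channel, the averaging of neighbouring unnamed spots and leaving out both arrays of 1 pyrethrin control extract were added after seeing the data.

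The procedure was tested on simulated arrays with the same layout. The simulated pyrethrin arrays carried exactly the mean dye effect, without a departure of their own. Of 50 features changed by 1 on the log2 scale per treatment, 96% were called for the pepper extract, 94% for the combination and 92% for pyrethrin, and of those changed by 0.5 it called 50%, 46% and 44%. The same runs gave 2, 10 and 41 false calls. Each treatment was given 200 changed features, most of them changed by 1 or more, which eases the adjusted threshold for the smaller changes. With few real calls, fewer changes of 0.5 would be found than these shares. A feature of median standard error that passed alone would need a change of 0.88 for the pepper extract, 0.87 for the combination and 0.92 for pyrethrin. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.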

Results

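RNA of whole female flies was compared with RNA of ethanol-treated flies on 20 arrays, 8 for the pepper extract at 0.2 mg/mL, 8 for the combination of pepper extract at 0.1 mg/mL and pyrethrin at 0.004 mg/mL, and 4 for pyrethrin at 0.04 mg/mL. Each treatment had 4 treated extracts, called units here, and values are log2 ratios of treated over control unless stated otherwise. Of 16896 features, 11526 were measured often enough to be tested, 2169 of them with a gene symbol. The number of units limits the precision; the median standard error of a log2 fold change was 0.124 for the pepper extract, 0.123 for the combination and 0.13 for pyrethrin. The labels do not state the direction of the deposited ratio, and 48 of the 61 named gene results turn sign where the values are read by channel (Cy5 over Cy3) instead.

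Cyp12d1-p, a cytochrome P450 known to respond to foreign compounds, was 1.31-fold higher after the pepper extract than after ethanol (log2 0.39 ± 0.10 SE, n = 4) and was above the control in 4 of 4 units. Among the other genes with the smallest p-values, Pi4KIIIalpha, a phosphatidylinositol 4-kinase, stood at 0.40 ± 0.10 (SE, n = 4) and Sgp at 0.79 ± 0.20 (SE, n = 4). RyR, the calcium release channel of the endoplasmic reticulum, stood at 0.50 ± 0.16 (SE, n = 3; 0.22 without replicate 3, 0.24 without the 2 arrays with foreign titles), SdhCL, related to a membrane subunit of succinate dehydrogenase, at 0.52 ± 0.13 (SE, n = 3), and sotv, which builds heparan sulfate chains, at 0.30 ± 0.10 (SE, n = 4). CG10738 stood at 0.60 and CG7115 at 0.51 (0.26 without replicate 3, 0.21 without these 2 arrays), while CG15711 at -0.46 and CG11970 at -0.36 (-0.23 without them) were the 2 named genes below the control. All 10 had a limma adjusted p of 1 over all features.

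With limma, 0 of the 11526 features passed an adjusted p of 0.05 for the pepper extract. At an unadjusted p under 0.05 there were 377 features, 208 above and 169 below the control, where chance alone gives 576.3, and the fit of all 20 arrays called 0 as well, with 391 at an unadjusted p under 0.05. Cyp12d1-p, fixed in advance because publications of the study name induced P450 genes, had a limma adjusted p of 0.00232 over the 3 treatments. If those publications rest on these same arrays, that p-value is not an independent test. Where the values are read by channel, the value of Cyp12d1-p was -0.26 and 2264 features passed.

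All 6 measured heat shock proteins and chaperones were above the control after the pepper extract, with a median of 0.21, among them Hsc70-2 at 0.45, Hsp68 at 0.32 and Hsc70-1 at 0.30, and 0 of them passed over all features or adjusted over the list alone. The same list also had a median of 0.999 along the main axis of variation between units, which runs across the treatments. It did not pass (adjusted p = 0.302, and adjusted p = 0.669 with an estimated correlation). Of the 4 measured cytochrome P450 genes, Cyp12d1-p passed adjusted over the list alone and 0 passed over all features; Cyp4ac1 at 0.02, Cyp6u1 at 0.01 and Cyp4g15 at 0.09 lay close to the control, and the list had an adjusted p of 0.302 (adjusted p = 0.369 with an estimated correlation). The antioxidant enzymes had 6 of 7 members above the control with a median of 0.03, and the glutathione S-transferases, which conjugate foreign compounds, had 0 of 3 above it with a median of -0.05. The UDP-glucuronosyltransferases had a median of 0.02 over 5 genes and the muscle contractile proteins 0.06 over 7, with Tm2 at 0.41. The fat body and hemolymph proteins had a median of 0.08 over 4 genes, and the genes of fatty acid and phospholipid metabolism 0.02 over 10. The circadian clock genes had a median of -0.02 over 5 genes and the cuticle proteins -0.04 over 8. None of the 20 lists passed for this treatment, and the adjusted p of these lists other than the P450 and heat shock lists was 0.825.

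After the combination, Cyp12d1-p was 1.40-fold higher than after ethanol (log2 0.48 ± 0.10 SE, n = 4), again in 4 of 4 units. Nmda1 stood at 0.35 ± 0.09 (SE, n = 4), CG17002 at 0.36, CG8032 at 0.31 and U4-U6-60K, a splicing factor, at 0.30. Below the control were bsf, an RNA-binding protein of mitochondria, at -0.50 ± 0.12 (SE, n = 4), the nucleosome assembly protein Nap1 at -0.37 and Nop60B, a pseudouridine synthase of ribosomal RNA, at -0.42. CG31294 stood at -0.50 and dan, a nuclear protein of the antenna, at -0.63 with the widest spread of the 10 (SD 0.689; -0.31 without replicate 4). Each of these genes had 1 sign in all 4 units, and their limma adjusted p ran from 0.425 to 0.471.

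For the combination 0 of 11526 features passed in limma. At an unadjusted p under 0.05 there were 1003 features, 570 above and 433 below the control, and the fit of 20 arrays called 0, with 1198 at an unadjusted p under 0.05. Cyp12d1-p had a limma adjusted p of 0.00081 over the 3 treatments and of 0.425 over all features. Without replicate 4 of the combination 4 features passed and without replicate 6 it was 1. With the values read by channel 1918 passed, and Cyp12d1-p stood at -0.19.

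In the combination the genes of stress and damage signalling were above the control in 5 of 5 cases with a median of 0.12, led by puc, a phosphatase of the JNK pathway, at 0.29 ± 0.10 (SE). The nuclear-encoded genes of oxidative phosphorylation were below the control in 6 of 8 cases with a median of -0.13, and ATPsynGL stood at -0.31. On the main axis of variation between units, which runs across the treatments, this list had a median of -0.82. Proteasome genes had a median of -0.05 over 15 and genes of the fasting and insulin response 0.06 over 5, with the lipase gene CG5966 at 0.50. The adjusted p was 0.567 for the first 2 of these lists, 0.584 for the proteasome and 0.825 for the fasting and insulin response, and 0 of their members passed over all features or adjusted over the list alone. The P450 list had an adjusted p of 0.304 (adjusted p = 0.369 with an estimated correlation), Cyp12d1-p being the member that passed adjusted over the list alone. Glycolysis and gluconeogenesis had a median of 0.10 but a mean of -0.02 and a downward test over 4 genes, since Tps1, which makes trehalose, stood at -0.48; on the axis across treatments its median was 0.76. None of the 20 lists passed for the combination.

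After pyrethrin, dsx, the transcription factor gene of sex determination, rose 1.61-fold (log2 0.69 ± 0.10 SE, n = 4, limma adjusted p = 0.0254; log2 1.22 without the dye correction), and ocn, a gene of the testis, rose 2.07-fold (log2 1.05 ± 0.18 SE, n = 4, limma adjusted p = 0.0476), each in 4 of 4 units. Vps51, of a complex that tethers vesicles at the Golgi, stood at 0.49 ± 0.09 (SE, n = 4) with a limma adjusted p of 0.0716 and did not pass (0.047 to 0.0499 in the 3 alternatives where it did). Cyp12d1-p stood at 0.39 ± 0.11 (SE, n = 4), 1.31-fold above the control in 4 of 4 units. CG14762 at 0.45, l(1)G0469 at 0.40 and beat-IV at 0.36 (0.07 without the dye correction) were the other named genes above the control. Below it were Gpdh3, a glycerol-3-phosphate dehydrogenase, at -0.47, CG30487 at -0.42, CG15772 at -0.38 (-0.19 without the dye correction) and CG4294 at -0.33, and these 7 genes had limma adjusted p-values of 0.249 to 0.255.

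In limma 7 of 11526 features passed for pyrethrin, 7 up and 0 down, of which 2 carried a symbol. The largest of the unnamed ones were the neighbouring spots ID12945 and ID12946, at 1.10 and 1.07 (both limma adjusted p = 0.0254), and the other 3 rose by 0.75 to 0.82; they are given because so few features passed, after their values were seen. At an unadjusted p under 0.05 there were 1151 features, 626 above and 525 below the control. Cyp12d1-p had a limma adjusted p of 0.00275 over the 3 treatments and of 0.255 over all features. Read by channel it stood at -0.17. Without the dye correction it stood at 0.61 and passed over all features (limma adjusted p = 0.0285). These calls leave out the error of the dye correction: simulated arrays without any change gave a median of 1069 features at an unadjusted p under 0.05 and 0 to 3 calls. The fit of 20 arrays counts that error and called 0, with dsx at an adjusted p of 1 and ocn at 0.315. It was too strict in the same simulations (a median of 241.5 features, where chance alone gives 576.3). With simulated changes it still called 151 changed features and 0 unchanged ones, where the main fit made 41 false calls. All these simulations gave the pyrethrin arrays exactly the mean dye effect, so they cannot show how strict either fit is on the real arrays. In fits that also had no control block, the calls fell to 0 without replicate 1, without replicate 4 or without both arrays of control extract 4 and to 1 without replicate 5, without both arrays of control extract 3 there were 7 calls of which 0 were shared, ocn did not pass without any 1 of the 4 units (adjusted p = 0.0632 to 0.185), and read by channel dsx was -1.30 and ocn -0.66.

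**Figure D1:**
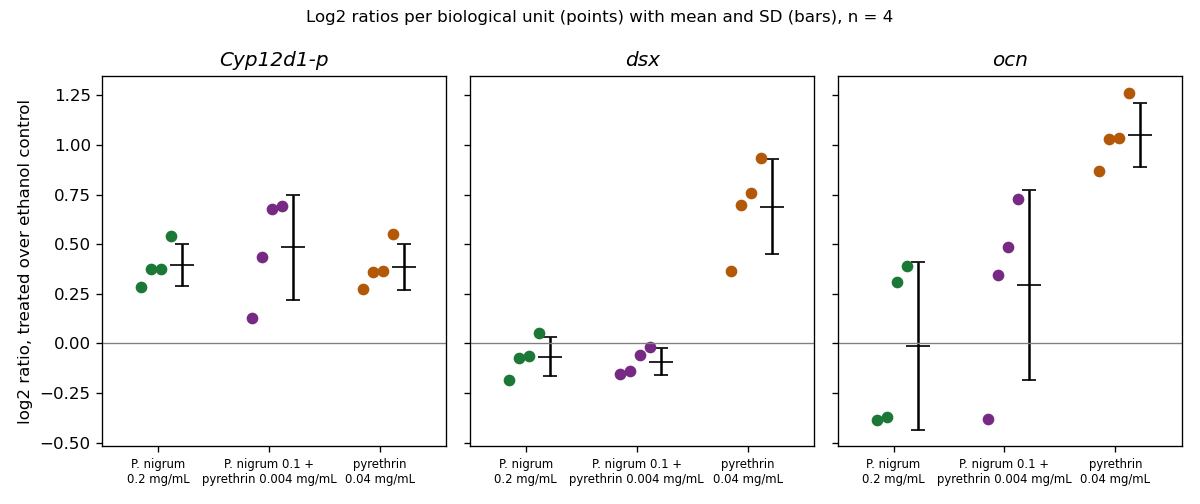
Log2 ratios of treated over ethanol control (vertical axis) of Cyp12d1-p, dsx and ocn for each of the 12 units (points), by treatment (horizontal axis), with the mean and SD of 4 units as bars. Cyp12d1-p is above 0 in 12 of 12 units, and the means of dsx and ocn after pyrethrin are 0.69 and 1.05. Where the values are read by channel, Cyp12d1-p turns negative in all 3 treatments, and dsx and ocn turn negative after pyrethrin.

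The male accessory gland and testis genes, kept as markers of male flies among the females, were above the control in 4 of 4 cases after pyrethrin with a median of 0.25, the one list of the 60 tests that passed (adjusted p = 0.023). It did not pass with an estimated correlation (adjusted p = 0.115), nor without pyrethrin replicate 1 (median 0.14, adjusted p = 0.228) or 5 (adjusted p = 0.147). Nor did it pass without the dye correction (median 0.10, adjusted p = 0.645), without the 2 arrays with foreign titles (median 0.17, adjusted p = 0.0991) or without control extract 3 or 4 (median 0.22 and 0.40, adjusted p = 0.182 and 0.357). Of its members, ocn alone passed, over all features and adjusted over the list alone; Acp36DE, a seminal fluid protein, stood at 0.35, the sperm tail gene dj at 0.15 and Acp53C14a, another seminal fluid protein, at 0.06. After the pepper extract the same list had a median of 0.01 but a mean of -0.01, and after the combination a median of -0.12. The phototransduction genes were below the control in 4 of 4 cases after pyrethrin, with a median of -0.15 (adjusted p = 0.584). The voltage-gated channels and other genes of neuronal excitability, which include the ion channel genes Sh at -0.06, Shab at -0.03 and cac at 0.05, had a median of -0.06 over 9 genes (adjusted p = 0.88). Of the 9, 3 were above the control and 1 had an unadjusted limma p under 0.05. The cytosolic ribosomal proteins had a median of 0.10 over 6 genes and the odorant-binding proteins 0.07 over 15 (adjusted p = 0.825 for each), and on the axis across treatments their medians were -0.52 and -0.57. The heat shock proteins and chaperones had a median of 0.09 over 6 genes (adjusted p = 0.825), with Hsp68 at 0.52, and passed where the dye correction was left out (median 0.51, adjusted p = 0.00283).

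Lists with fewer than 3 measured members were not tested. The yolk protein receptor gene yl, the one measured gene of the ovary list, stood at -0.15 after the pepper extract, -0.29 after the combination and 0.04 after pyrethrin. The gut lipase gene mag stood at -0.11, -0.01 and -0.09, and the hemocyte genes Pxn and NimC1 at -0.13 and -0.19 after the pepper extract. The P450 genes known to respond to foreign compounds had Cyp12d1-p as the 1 measured member. Esterases, ABC transporters, antimicrobial peptides, Turandot genes, mitochondrial-encoded transcripts and histones with cell cycle genes had 0 measured members and are not analysed here.

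**Figure D2:**
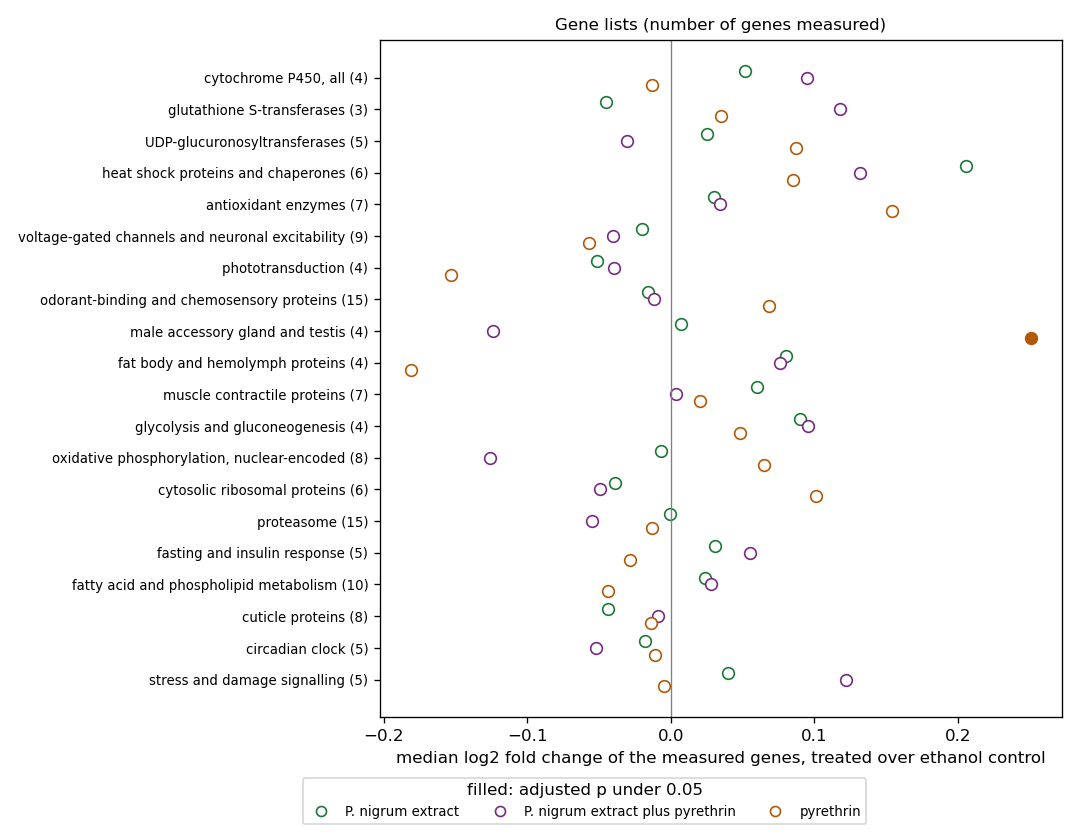
Median log2 fold change of treated over ethanol control (horizontal axis) of the measured genes of each of 20 gene lists (vertical axis, number of genes in brackets), 1 point per treatment, filled where the adjusted p with the preset correlation is under 0.05. The filled point is the male list after pyrethrin at 0.25, which has an adjusted p of 0.115 with an estimated correlation and turns sign where the values are read by channel.

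The combination was compared with the pepper extract alone at its higher dose. SdhCL stood at -0.22 after the combination (SD 0.158, n = 4) and 0.52 after the extract (SD 0.256, n = 3), a difference of -0.73 ± 0.17 (SE). Orai, the store-operated calcium channel, stood at -0.32 and 0.21, a difference of -0.53 ± 0.16 (SE). The differences of CG8032 at 0.43, botv, which builds heparan sulfate chains, at 0.45, siz at 0.44, BCAS2 at 0.45 and CG10669 at 0.38 were positive. Those of CG18858 at -0.52, CG11379 at -0.38 and ChLD3, a chitin deacetylase-like gene, at -0.37 (-0.56 without the 2 arrays with foreign titles) were negative. The limma adjusted p was 0.886 for SdhCL and 0.978 for the other 9 genes, and 0 of 11526 features passed, with 534 at an unadjusted p under 0.05. The fit of 20 arrays called 0, with 554 at an unadjusted p under 0.05, the replicate block gave 0 with 820, and the values read by channel gave 235.

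The combination was compared with pyrethrin alone at its higher dose. The mean of dsx was -0.09 after the combination (SD 0.067, n = 4) and 0.69 after pyrethrin (SD 0.239, n = 4), a difference of -0.78 ± 0.14 (SE). Vps51 stood at -0.08 and 0.49, a difference of -0.57 ± 0.13 (SE), and Cyp1, a cyclophilin, at -0.25 and 0.33, a difference of -0.58 ± 0.14 (SE). The differences of Orai at -0.64 (-0.35 without the dye correction or without control extract 4), Nap1 at -0.57 and CG9257 at -0.44 were negative too. Those of CG15196 at 0.96 (0.56 without control extract 4), CG15772 at 0.67, CG18135 at 0.57 and GCS2alpha, a glucosidase of glycoprotein folding, at 0.67 were positive. The limma adjusted p ran from 0.19 for dsx to 0.273, and 0 of 11526 features passed, with 1391 at an unadjusted p under 0.05. The fit of 20 arrays called 0 with 725 and the replicate block 0 with 2602; without the dye correction 1 feature passed, dsx at -1.31, without pyrethrin replicate 2 also 1, and read by channel 43 did.

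Pyrethrin was also compared with the pepper extract. The difference was 0.76 ± 0.14 (SE) for dsx, whose mean was 0.69 after pyrethrin and -0.07 after the extract (SD 0.098, n = 4), and 1.06 ± 0.24 (SE) for ocn, whose mean after the extract was -0.01 (SD 0.421, n = 4). The difference of Vps51 was 0.63 ± 0.13 (SE). Spn, the spinophilin gene, differed by 1.04, CG16772 by 1 and tay by -0.86, and without pepper extract replicate 1 these were 0.62, 0.67 and -0.57. The differences were 0.51 for l(1)G0469, 0.40 for CG12880, -0.61 for GCS2alpha and -0.44 for sotv. The limma adjusted p ran from 0.621 for dsx and Vps51 to 0.839, and 0 of 11526 features passed, with 648 at an unadjusted p under 0.05. The fit of 20 arrays called 0 with 272 and the replicate block 0 with 791; without the dye correction 1 feature passed, dsx at 1.28, without pepper extract replicate 4 also 1, and read by channel 9 did.

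Cyp12d1-p did not differ between treatments by more than its error. Its differences were 0.09 ± 0.14 (SE) for the combination minus the pepper extract, 0.10 ± 0.15 for the combination minus pyrethrin and -0.01 ± 0.15 for pyrethrin minus the pepper extract, with limma adjusted p-values of 0.994, 0.827 and 0.996. Over the 12 units its mean was 0.42 with an SD of 0.167 and it was above the control in 12 of 12 (exact two-sided sign-flip p = 0.000488 with 12 independent signs, the smallest they can give). The pyrethrin units share 2 control extracts and 1 dye correction, and with these 4 flipped together the exact two-sided p was 0.00391, the smallest that 9 signs can give.

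The fold changes of the treatments were related weakly across features, which are not independent replicates because duplicate spots are among them. Pearson's r was 0.119 between the pepper extract and the combination (rho = 0.114, 54% of features with the same sign). It was 0.044 between the pepper extract and pyrethrin (rho = 0.013, 49.9%) and -0.141 between the combination and pyrethrin (rho = -0.174, 43.8%). No called feature could be shared, since 2 of the 3 treatments had 0 calls. At an unadjusted p under 0.05 the numbers of shared features are given beside those of independent lists and of simulated arrays with no change; they were not tested, because duplicate spots are not independent and the dye correction of the pyrethrin arrays comes from the arrays of the other treatments. The pepper extract and pyrethrin shared 41 features above the control, against 11.3 for independent lists and 14 to 28 in the simulations, and 20 below it, against 7.7 and 15 to 24. The pepper extract and the combination shared 16 above the control, against 10.3 and 12 to 17, and 15 below it, against 6.3 and 8 to 24. The combination and pyrethrin shared 33 above the control, against 31 and 16 to 23, and 30 below it, against 19.7 and 9 to 27. The simulated lists had other lengths than the real ones, so a count outside a simulated range is no excess by itself. With these lengths independent lists share a median of 12.7 features above and 14 below the control for the first pair, 6.8 and 7.3 for the second and 12.6 and 13.5 for the third. The simulated r ran from -0.026 to 0.027 for the pepper extract and the combination, from -0.03 to 0.017 for the pepper extract and pyrethrin and from -0.022 to 0.019 for the combination and pyrethrin. The simulations drew every feature independently, without the main axis across the treatments and without correlated duplicate spots. Real units of different treatments correlated at -0.446 to 0.444. The simulated ranges of r and of shared features are therefore too narrow, and a real value outside them is no sign of a relation between treatments.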

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

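The tests of Cyp12d1-p, of dsx and ocn and of the position on the slide were chosen only after the result was seen, while those of the ovary share, of gene length and of the regroupings of units were not. In 6 of 75 groups of 4 gene values 1 unit lay far from the other 3, and in 0 of 6 groups of array measures; chance alone gives about 1 in 20, here 4.05. After the pepper extract these were CG11970 in replicate 3 (-0.685, nearest other unit -0.291), botv in replicate 4 (-0.541, nearest -0.113) and CG16772 in replicate 1 (-1.298, nearest -0.048). The others were CG15196 in replicate 5 of the combination (1.035, nearest 0.255) and, after pyrethrin, Cyp1 in replicate 2 (-0.025, nearest 0.436) and CG9257 in replicate 1 (0.436, nearest 0.189).

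Cyp12d1-p was above its ethanol control in 12 of 12 units. The exact two-sided sign-flip p was 0.000488 with 12 independent signs. It was 0.00391 with the 4 pyrethrin units, which share controls and a dye correction, flipped together. The gene was fixed from publications that may rest on these same arrays, so these p-values do not settle chance over the units. A dye bias as the whole source is argued against under the direction used here. The mean was above 0 with the treated RNA in Cy5 (0.213, SE 0.099, 5 of 8 arrays above 0, exact two-sided sign-flip p = 0.0625). With the treated RNA in Cy3 it was above 0 too (0.67, SE 0.086, 8 of 8, exact two-sided sign-flip p = 0.00781). The gap between both orientations is itself a dye effect. If the deposited values were fixed by channel, values above 0 in both orientations could be a dye bias of the spot. The treatment effect would then be -0.26 for the pepper extract, -0.19 for the combination and -0.17 for pyrethrin. RNA of the neighbouring copy Cyp12d1-d cannot be told apart from it, since 0 spots carry the name of that copy alone. A response to the sprayed compounds stays open as a hypothesis, for 1.31-fold to 1.40-fold changes.

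After pyrethrin, dsx and ocn were above their controls in 4 of 4 units on arrays of 1 dye orientation. A dye bias alone would have to be -1.22 for dsx and -0.80 for ocn, outside the 8 exchanged pairs, which ran from -0.93 to 0.02 and from 0.09 to 0.51. For ocn, male flies in the treated extracts would raise other male transcripts alike, but the median of the other 3 markers was 0.154 (SE of their mean 0.086) against 0.525 for 0.5 of the value of ocn. That SE is a spread over 3 genes, and the bar was set after ocn had been seen, so the check is weak. It does not cover dsx. With either control extract alone the values were at least 0.561, each at least 4 of its standard errors above 0, though neither gene passed. Those standard errors leave out the error of the dye correction, which the arrays of both control extracts share. The values therefore do not settle whether a single control extract was odd. Open is the error of the dye correction, with which neither gene passes (adjusted p = 1 and 0.315 in the fit of 20 arrays). That fit was too strict in simulations, but these gave the pyrethrin arrays exactly the mean dye effect and cannot show its strictness here. Open too are an odd control extract, a reading by channel, which turns both signs, and pyrethrin itself.

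The main axis of the 12 units held 31% of the variation of 10017 features and ran across the treatments, with its largest weights in the combination units 4 (0.57) and 6 (-0.44), and with chaperones at its high end (Hsc70-1 at 1.84, heat shock list median 0.999) and odorant-binding proteins (median -0.57) and oxidative phosphorylation (median -0.82) at its low end. Position on the slide is argued against, since unrelated neighbouring spots shared the loading with r = 0.19 against 0.894 for duplicate spots, across features. A varying share of ovary stays open: 12 germline markers had a median loading of -0.194 inside the range of random lists (-0.316 to 0.31), but they go both ways (png at 0.909, mael at -0.933), so the median decides nothing, although it had been written down beforehand as evidence against. Gene length, as the genomic span, goes with the loading (Spearman's rho = 0.178 across 1931 genes, which are not independent), so a difference in RNA length or integrity between extracts may contribute. Apart from the ovary share no biological explanation was tested.

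Regroupings of the units were counted for each comparison. They exchange the pyrethrin units as if these were independent, although they share 2 control extracts and 1 dye correction, so the shares with pyrethrin are approximate. Turning the signs of 4 units gives 8 patterns, too few for a share under 0.05. A real count of 0 calls is reached by every pattern or split, so it tests nothing; this was so for 8 of 8 patterns of the pepper extract and 8 of 8 of the combination, with 0 as the highest other in both. For pyrethrin it was 1 of 8, with 7 calls in the real pattern and 0 as the highest other. A real count of 0 was found too for the differences between treatments, reached in 35 of 35 splits each, and the highest other counts were 0 for the combination minus the pepper extract, 203 for the combination minus pyrethrin and 0 for pyrethrin minus the pepper extract. Among the sign patterns, the highest other count at an unadjusted p under 0.05 was 512 for the pepper extract (377 real). It was 2048 for the combination (1003 real) and 1108 for pyrethrin (1151 real). At an unadjusted p under 0.05 as many features as in the real split came from 12 of 35 splits for the combination minus the pepper extract (534 real, 2764 highest other). It was 5 of 35 for the combination minus pyrethrin (1391 real, 2667 highest other) and 5 of 35 for pyrethrin minus the pepper extract (648 real, 1586 highest other). From these counts at an unadjusted p, chance cannot be excluded for any of the differences, and the splits with many more features than the real one point to a structure of the units, of which the axis across the treatments is a part.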

How the results depend on the processing

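The reading by channel, the averaging of neighbouring unnamed spots and leaving out both arrays of 1 pyrethrin control extract were tests chosen only after the result was seen. Of 1645 alternative values of the 61 named gene results, 1597 kept the sign, and the other 48 were all under the reading by channel. Many alternatives, such as no block, cannot move an estimate, so kept signs are weak evidence. Of the values, 17 no longer passed, 8 newly passed and 11 turned with a pass in at least 1 reading. For the 60 gene list results, 7 alternatives no longer passed, 1 newly passed and 6 turned with a pass. Precision is limited by 4 units per treatment and by arrays whose duplicate spots correlated at as little as 0.172. Signal and background were not used here, and the cause of a change was not tested where none is given.

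The 7 calls for pyrethrin became 15 on a common scale, 3 with single spots, 13 with all 4 units measured, 4 with at least 2 units, 15 without the control block and 12 without weights. With single spots 0 of the calls carried a symbol, so neither dsx nor ocn was among them. Without the dye correction they were 132, with 1 call each for the combination minus pyrethrin and pyrethrin minus the pepper extract, since the dye effect then stays in the values. They were 0 with the nearest dye effect and 0 in the fit of 20 arrays. In the latter dsx and ocn kept their estimates and the spread grew by construction. It was too strict for pyrethrin in simulations, whose pyrethrin arrays carried exactly the mean dye effect. Control extract 4 left out gave 0 for pyrethrin, with fewer units. Control extract 3 left out gave 1 call for the combination minus pyrethrin and 7 for pyrethrin (4 up, 3 down), of which 0 were shared with the 7 reported, and dsx and ocn did not pass (adjusted p = 0.163 and 0.211). In these 2 fits and in the 4 without 1 pyrethrin unit, the 1 shared control extract left no correlation to estimate, so no block was used, and their counts mix both changes. Over all alternatives that kept its sign, the adjusted p of dsx reached 1 and that of ocn 0.597. Also, dsx did not pass without pyrethrin replicate 1 or 4 (0.126 and 0.106), and ocn not without any of the 4 pyrethrin units (0.0632 to 0.185) or without combination replicate 5 or 6 (0.0596 and 0.068). With at least 2 units measured ocn did not pass either (0.0604).

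Leaving out each unit gave 0 to 4 calls for the combination (4 without its replicate 4, 1 without replicate 6) and 0 to 10 for pyrethrin (0 without its replicate 1 or 4, 1 without replicate 5). It gave 0 to 1 for the combination minus pyrethrin (1 without pyrethrin replicate 2) and 0 to 1 for pyrethrin minus the pepper extract (1 without pepper replicate 4). The median of the male list after pyrethrin ran from 0.136 to 0.333, and it did not pass without pyrethrin replicate 1 or 5 (adjusted p = 0.228 and 0.147).

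Read by channel, the calls were 2264 for the pepper extract, 1918 for the combination, 90 for pyrethrin, 235 for the combination minus the pepper extract, 43 for the combination minus pyrethrin and 9 for pyrethrin minus the pepper extract. Of the 48 named results that turned, the 11 past the threshold in at least 1 reading were Cyp12d1-p (-0.26, pepper extract), Nmda1 (-0.33), Nap1 (0.27) and Nop60B (0.32) in the combination, dsx (-1.30) and ocn (-0.66) after pyrethrin, botv (-0.42), ChLD3 (0.48) and CG18858 (0.68) for the combination minus the pepper extract, dsx (1.10) for the combination minus pyrethrin and ocn (-0.83) for pyrethrin minus the pepper extract. Lists that turned and passed in at least 1 reading were, by median, heat shock (-0.71 pepper extract, -0.37 pyrethrin), odorant-binding (0.17), muscle (0.19) and oxidative phosphorylation (0.23) in the combination, and the male list (-0.19) after pyrethrin.

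The male list after pyrethrin did not pass with an estimated correlation (median 0.25), without the dye correction (0.10), without the 2 arrays with foreign titles (0.17) or without control extract 3 (0.22) or 4 (0.40), with adjusted p from 0.0991 to 0.645. Heat shock genes after pyrethrin passed without the dye correction (0.51).

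With the replicate block, 0 features differed in each of the 3 differences between treatments, as without it, over the 11101 features with every term estimated. Of 8 pairs of units with the same number in 2 treatments, 1 had r over 0.1 and 0 correlated best with their own number (median r = -0.152 across features, against 0.064 for other numbers), so the numbers do not pair the units.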

Other observations

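The fit of 1 mean over all units, the hypothesis of a common response and its sign flips were chosen only after the result was seen. Across the 12 units, 22 of 10017 fully measured features had 1 sign in all units. Chance gives 4.9 with 12 independent signs, 19.6 with 1 sign per control extract and 39.1 with the 4 pyrethrin units as 1 sign, and duplicate spots count separately. The pyrethrin units correlated at -0.01 to 0.26 across features, neither independent nor alike, so whether 22 exceeds chance stays open. With 1 mean over all units, 5 features passed in limma, 2 above and 3 below the control. Cyp12d1-p came first at 0.42 ± 0.06 (SE, n = 12, limma adjusted p = 0.00774), and the neighbouring unnamed spots ID16399 at -0.57 and ID16400 at -0.54 had the same adjusted p. Sgp stood at 0.59 above the control in 11 of 12 units, with a limma adjusted p of 0.115.

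A common response to all 3 treatments may be present as a hypothesis: of 100 sign patterns of the units, the real one included, 1 gave as many as 5 features, and the highest of the others gave 2. With the pyrethrin units flipped together it was again 1 of 100, with 2 as the highest other. Across all features the 3 treatments do not all move alike: the combination and pyrethrin had r = -0.141 with 43.8% of the same sign, and the pepper extract and pyrethrin r = 0.044 with 49.9%. The pepper extract and the combination went weakly together, with r = 0.119 and 54% of the same sign. How many features a response common to all 3 treatments would concern was not tested. The error of the units and the main axis across the treatments enter these correlations, so they cannot limit its extent. If the deposited values were fixed by channel, the average of both orientations could be a dye bias of the spots. Under that reading Cyp12d1-p was -0.26 after the pepper extract, -0.19 after the combination and -0.17 after pyrethrin.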
